A study of Homo sapiens with 24 samples.

How the data were processed

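The series measured mRNA in HMLE cells, an immortalized human mammary epithelial line, that carried either LacZ, a bacterial enzyme gene used as the control, or RBMS3, an RNA-binding protein. Per the labels' protocols, actinomycin D, which blocks transcription, was given to both lines at 10 µg/mL for 0, 90, 180 or 360 min, and libraries were made with QuantSeq, which reads the 3' end of polyadenylated RNA. The 24 libraries fall into 8 groups of 3, one group for each line and time, taken from the sample titles and treatment labels. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

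Per the submitters' processing notes, the tools included Trim Galore 0.6.6, Salmon 1.4.0 and DESeq2 1.32.0; the genome build and annotation are not given in the sources used here. The authors deposited a series-wide table with a normalized signal for each of 38849 genes and 24 libraries, which is the main source of values here and is called the normalized count below. They also deposited, for each library, an estimated count and a TPM value for each of 231288 transcripts, per the file headers. The estimated counts were summed over genes and used for a label check, the factor between table and reads, the replicate spread, edgeR comparisons of RBMS3 cells at 180 and 360 min against 90 min, and a repeat of the slope fit, and the TPM values deposited by the authors were not used.

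The record that attaches a transcript file to a sample and the name of that file disagreed for 12 of the 24 samples. Each attached file was therefore compared across 11967 genes with every column of the table: it correlated best with the column of its own name (Pearson r 0.919 to 0.938 across genes, next best at most 0.911, smallest gap 0.024), so the table's columns, matched to samples by title, were used throughout. Of the transcripts, 88.4% matched the reference annotation used for gene names, with 95.1% to 95.7% of the estimated reads of a library.

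The normalized counts are not whole reads divided by a size factor. After division by the value of 1 read in a library, 37.4% to 45.8% of the values under 50 reads lay within 0.02 of a whole number, so no count test was run on the table. A factor that differs between genes and libraries remained between the table and the estimated reads in the 12 libraries with an undisputed file: over 8274 genes its range across libraries had a median of 1.25-fold and exceeded 1.5-fold in 37.9% of the genes. Normalized counts summed to 6638187 to 8080428 per library, the implied depth was 4405790 to 9727284 reads, and 14193 to 15697 genes were above 0. Depth estimated from the transcript files was 4426445 to 9856338 reads. Where every library of a group was at 0, folds are lower bounds against a floor of 3 reads per library. Such floors cover counting error only.

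Differences were tested with limma 3.58.1 in R 4.3.3 (trend on, robust off) on log2(normalized count + 1), with 8 group means in 1 fit and Benjamini-Hochberg adjustment over the 12096 genes whose mean over all libraries was at least 10. A gene passed at an adjusted p under 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates changes of low genes. The comparisons were RBMS3 against LacZ cells at each time, each later time against 0 min within each line, and the difference in slope, a linear contrast over 0, 1.5, 3 and 6 h in log2 per hour, RBMS3 minus LacZ. All values are relative to the other transcripts of a library, since total RNA per cell was not measured, so a rise after transcription is blocked is a gain in share of the library, whatever its source.

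There were 23 gene lists: EMT transcription factors with the RBMS family, mesenchymal, epithelial, basal mammary, luminal mammary, leukocyte or endothelial, immediate early and labile, inflammatory AU-rich, KRAB zinc finger, cytosolic ribosomal protein, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, p53 targets, G2/M cell cycle, S phase, interferon response, TGF-beta pathway, Wnt pathway, cholesterol synthesis, unfolded protein response, heat shock, and RNA decay and AU-rich binding. They hold 694 different genes. The 22 lists with at least 5 tested genes were tested with camera (inter-gene correlation 0.01, and again with an estimated correlation), adjusted over the lists of a comparison.

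Named genes follow a rule. It takes RBMS3 and PRRX1, and the 10 largest rises and falls among genes that passed. These needed a mean of at least 50 in the higher group and replicates that did not overlap. For slopes the mean was over all libraries and overlap was not a condition. Up to 4 members of each list are added by the same conditions, with all tested EMT factors. The groups, tests, lists, this rule and the other settings to be tried were fixed before the data were examined. Genes named to spell out a count of 5 or fewer, and those named for a change between 0 and 90 min, were chosen after their values were seen. Some genes that the rule selects are not reported here.

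On data simulated from the libraries' own means and spread, with 200 changed genes, the test of RBMS3 against LacZ cells at 0 min recovered 64% of changes of 1 log2 unit and 91% of changes of 2 among 11988 genes, with 3.73% false calls. The slope test recovered 48% and 77% of such changes over 6 h among 11991 genes, with 6.72% false calls. Recovery was not split by expression level or by the course of a change over time. These rates therefore describe the simulated changes, and may be too favourable for low genes or for changes that come early.

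Alternatives were other pseudocounts (0.5 and 5), other filters on low values, equal library totals, TMM factors (edgeR 4.0.16), scaling to the ribosomal protein genes, the replicate number as a block, fits on only the compared groups, a fold minimum, the list test fry, the interaction at 360 min alone, leaving out each library, and edgeR's quasi-likelihood test on rounded estimated counts for the RBMS3 cells at 180 and 360 min against 90 min. The slope without the 0 min libraries and the slope on estimated reads were added after the results were seen. For the latter each transcript file was taken for the column it correlated best with, a different one for each file, and libraries were scaled to equal totals or by a median ratio. Longest annotated 3' UTRs came from GENCODE 29. Figures and file handling used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.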

Results

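The 24 libraries hold polyadenylated RNA of HMLE cells that carried LacZ, the control, or RBMS3, a protein that binds AU-rich RNA. Each line was sampled before actinomycin D and after 90, 180 and 360 min of it, with 3 libraries for each line and time. The depth implied by the table was 4405790 to 9727284 reads per library, and 14193 to 15697 genes were above 0. Values below are normalized counts, given as mean ± SD of the 3 libraries of a group (n = 3) unless said otherwise, and differences are on the log2(normalized count + 1) scale. Gene positions are not printed because the genome build is not given in the sources used here. Libraries of a group correlated across genes at a Pearson r of at least 0.937, except in LacZ cells at 0 min, where the lowest r was 0.909 and involved replicate 2. The first principal component, with 46.5% of the variance, separated the lines, and the second, with 14.4%, ordered the libraries by time.

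The first question was whether the RBMS3 transcript was higher in the cells made to carry it. It stood at 75.7, 101 and 116 in the LacZ libraries at 0 min and at 358, 254 and 203 in the RBMS3 libraries. After 90 min the LacZ libraries held 48.7, 60.5 and 130.0 and the RBMS3 libraries 174, 236 and 219. At 180 min the values were 27.6, 97.0 and 59.2 against 179, 178 and 224, and at 360 min they were 73.3, 77.8 and 165 against 197, 236 and 201. Each of the 12 RBMS3 libraries thus lay above each of the 12 LacZ libraries. In limma the difference was 1.45 ± 0.39 (SE) at 0 min with an adjusted p of 0.0061, and 1.09 ± 0.39 at 360 min with an adjusted p of 0.035. A 3' tag reads an introduced coding sequence only where that construct ends like the endogenous gene, which the labels do not state, so these values need not measure the introduced copy.

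PRRX1, a transcription factor of mesenchymal cells that the series title names as a target of RBMS3, was nearly absent from LacZ cells and abundant in RBMS3 cells. At 0 min it was 6.64, 0 and 0 in the LacZ libraries and 472 ± 27.6 in RBMS3 cells, and the fold of the means was 213. The difference was 7.91 ± 0.50 with an adjusted p of 8.0e-11 in limma. All 9 later LacZ libraries were at 0. In RBMS3 cells PRRX1 was 482 ± 68.9 at 90 min, 501 ± 53.5 at 180 min and 541 ± 51.6 at 360 min, at least 156-fold, 155-fold and 172-fold higher than the floor of 3 reads per LacZ library. Within RBMS3 cells the 360 min value differed from that at 0 min by 0.20 ± 0.50 (SE), with a limma adjusted p of 0.80. This SE is pooled over all 8 groups and is set mostly by the LacZ libraries at 0 min (6.64, 0 and 0). It therefore does not measure the spread of the RBMS3 libraries compared. The difference in slope between the lines was 0.16 ± 0.11 per hour (limma adjusted p = 0.48), and with LacZ libraries at the floor, a difference in the loss of PRRX1 was not detectable at this depth.

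**Figure D1:**
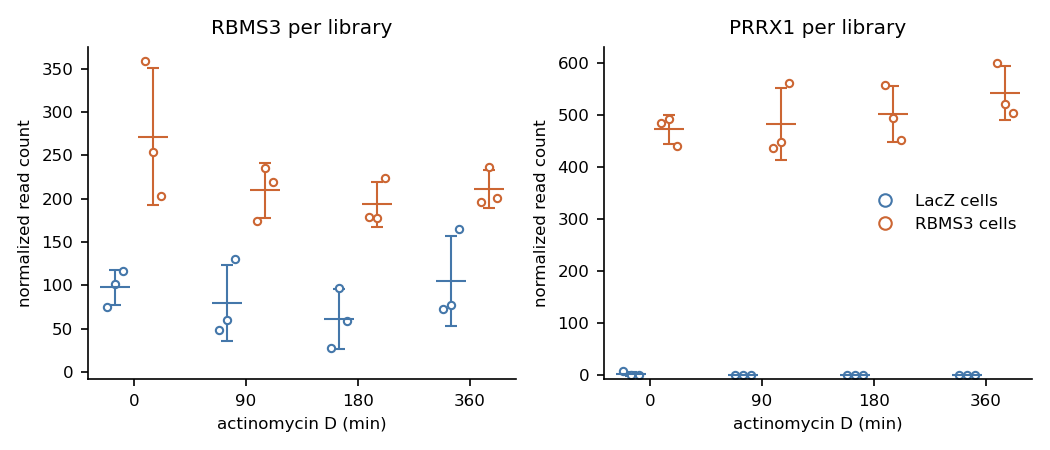
Normalized count of RBMS3 and of PRRX1 in each of the 24 libraries, by minutes of actinomycin D, with a bar at the mean of each group of 3. RBMS3 libraries held 472 ± 27.6 PRRX1 counts at 0 min and 541 ± 51.6 at 360 min, while 11 of the 12 LacZ libraries were at 0.

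Before actinomycin D, RBMS3 cells held mesenchymal transcripts that LacZ cells lacked, and many epithelial transcripts were near 0 in them. The elastic fibre protein gene FBLN5 was 3141 ± 54.7 in RBMS3 cells and 0.551 ± 0.955 in LacZ cells (log2 11.15, limma adjusted p = 2.1e-16), and the matrix proteoglycan gene BGN was 1544 ± 93.3 against 0.553 ± 0.957. POSTN, which codes for a secreted matrix protein, was 1775 ± 217 in RBMS3 cells and listed at 0 in every LacZ library, at least 625-fold higher. In the other direction, the epithelial adhesion molecule EPCAM was 1716 ± 30.3 in LacZ cells and 0.707 ± 1.22 in RBMS3 cells (log2 −10.20, limma adjusted p = 2.6e-11). ESRP1, a splicing regulator of epithelial cells, was 903 ± 132 in LacZ cells and 0 in all RBMS3 libraries, at least 297-fold lower. Of 12096 genes tested, limma called 2250 higher and 2284 lower in RBMS3 cells. Further large rises were in CADM3, a cell adhesion molecule (2469 ± 85.0, at least 869-fold), UCHL1, a deubiquitinase (624 ± 86.6, at least 220-fold), the chemokine receptor ACKR1 (573 ± 45.0, at least 202-fold), the basement membrane gene NID1 (516 ± 17.3, at least 182-fold), HHIP, an inhibitor of hedgehog signalling (1107 ± 291 against 3.45 ± 2.99), and COL3A1. This collagen gene was at 0 in LacZ cells and at 2000.1, 169 and 171 in the RBMS3 libraries, so 1 library set most of its mean. The other large falls were in MAL2, which sorts proteins in polarized cells (log2 −9.48), LAD1 (−9.06) and COL17A1 (−9.03), both of the epithelial basement membrane, and HOOK1 (−7.88). The protease gene KLK5, the cytokine gene IL1A, the sorting adaptor AP1M2 and the epithelial trafficking gene RAB25 were 485 ± 42.0, 436 ± 119.7, 337 ± 75.5 and 248 ± 35.5 in LacZ cells and 0 in RBMS3 cells, at least 159-fold, 143-fold, 111-fold and 81.5-fold lower.

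Of the 14 tested transcription factors of the epithelial-mesenchymal transition (EMT) and RBMS family members, 9 were higher, 2 lower and 3 not past the test, also when adjusted over the list alone (camera adjusted p = 0.0042). This list, called the EMT factors below, holds RBMS3 itself and PRRX1, both among the 9 higher. ZEB1, a repressor of epithelial genes, rose from 17.2 ± 2.96 in LacZ to 412 ± 10.2 in RBMS3 cells (log2 4.52). TWIST1 was 48.8 ± 11.3 against 662 ± 73.0 (3.76), TWIST2 46.1 ± 14.1 against 406 ± 31.7 (3.15), FOXC2 62.8 ± 6.01 against 488 ± 28.8 (2.94), ZEB2 9.59 ± 3.58 against 95.8 ± 26.6 (3.21) and TCF4 73.0 ± 24.3 against 336 ± 70.5 (2.22). RBMS1 was also higher (0.74), while RBMS2 (−0.53) and SOX9 (923 ± 192 against 129 ± 19.2, −2.82) were lower. SNAI2 (−0.18, limma adjusted p = 0.74), FOXC1 (−0.42, 0.17) and SOX4 (−0.17, 0.36) did not pass.

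Among 43 mesenchymal genes, 33 were higher, 3 lower and 7 not past the test (34 higher and 4 lower adjusted over the list alone), with a median log2 difference of 1.87 and a camera adjusted p of 4.1e-18. COL1A2, a chain of type I collagen, was 669 ± 46.5 in RBMS3 and 2.69 ± 4.67 in LacZ cells, and the fibrillin gene FBN1 1169 ± 21.7 against 8.88 ± 3.96. The 3 lower members, chosen after their values were seen, were the hyaluronan receptor CD44 (−2.51), the protease gene MMP14 (−1.87) and the cadherin gene CDH11 (−1.64). Of 35 epithelial genes 33 were lower and 1 was higher, also when adjusted over the list alone (median −3.74, camera adjusted p = 2.9e-25). The higher one was the keratin gene KRT7 (0.29). Of 21 basal mammary genes 15 were lower and 3 higher, also over the list alone (median −2.46, camera adjusted p = 2.5e-10). TP63, the p53-family factor of basal cells, was 247 ± 58.4 in LacZ and 3.28 ± 2.04 in RBMS3 cells, KRT6B was 163 ± 31.2 against 1.89 ± 3.27, and NGFR was 57.4 ± 2.81 against 0, at least 18.9-fold lower. The higher members, chosen after their values were seen, were KRT14 (1.26), DST (0.83) and BNC1 (0.68).

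Inflammatory transcripts with AU-rich elements were lower as a group, with 12 of 19 lower and 0 higher, also over the list alone (median −1.37, camera adjusted p = 2.1e-04). IL1B, an inflammatory cytokine, was 491 ± 79.1 in LacZ and 1.93 ± 2.47 in RBMS3 cells, HBEGF, a ligand of the EGF receptor, 1387 ± 193 against 114 ± 6.93, and ICAM1 90.2 ± 32.0 against 11.4 ± 4.97. Heat shock genes were lower in 7 and higher in 2 of 13, also over the list alone (median −0.57, camera adjusted p = 0.0027). The chaperone HSP90AB1 was 46742 ± 6206 in LacZ and 20192 ± 284 in RBMS3 cells (−1.20), and the higher members, chosen after their values were seen, were CRYAB (3.21) and HSPB1 (0.20). Lists of growth and energy metabolism were called higher by smaller amounts. Ribosomal protein genes were higher in 50 and lower in 7 of 78 (50 and 11 over the list alone, median 0.35, camera adjusted p = 2.9e-09), with RPLP2 at 17894 ± 204 against 7774 ± 859.7. Nuclear genes of oxidative phosphorylation were higher in 25 and lower in 3 of 44, also over the list alone (median 0.42, camera adjusted p = 1.0e-05), among them COX5A (1.03) and ATP5MC2 (1.01). The lower ones, chosen after their values were seen, were CYC1 (−0.35), UQCRB (−0.34) and NDUFB9 (−0.27). Glycolysis genes were higher in 10 and lower in 0 of 18 (11 and 0 over the list alone, median 0.44, camera adjusted p = 3.6e-05), with LDHA, which makes lactate, at 16352 ± 94.5 against 4829.5 ± 138 (1.76). G2/M genes were higher in 14 and lower in 1 of 25 (14 and 2 over the list alone, median 0.40, camera adjusted p = 0.0012), with the spindle gene NUSAP1 at 2022 ± 92.9 against 842 ± 129, while the mitotic kinase AURKB was lower (−0.91). With libraries scaled to the ribosomal protein genes instead, the median of all genes was −0.29, with 1336 genes then higher and 3824 lower in all. These medians became 0.12 for oxidative phosphorylation, 0.14 for glycolysis and 0.098 for G2/M. The ribosomal protein median of 0.046 is held near 0 by this scaling itself.

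The remaining lists were not called by camera at 0 min. Luminal mammary genes were higher in 3 and lower in 5 of 8 (camera adjusted p = 0.12), with MUC1 up (4.32) and WFDC2 (−5.50), ALDH1A3 (−3.98) and KRT15 (−2.77) down. Mitochondrially encoded genes were lower in 6 and higher in 1 of 13 (camera adjusted p = 0.085). The lower ones included MT-ND6 (1559 ± 47.1 against 395 ± 17.5), and the higher one, chosen after its value was seen, was MT-CO1 (0.28). Cholesterol synthesis genes were higher in 9 and lower in 4 of 21 (0.15), and genes of RNA decay and AU-rich binding were higher in 2 and lower in 13 of 35 (0.058), IGF2BP1 among the lower (−1.37) and CNOT7 among the higher (1.16). Wnt genes were higher in 4 and lower in 9 of 21 (5 and 10 over the list alone, 0.16), with the antagonist SFRP1 down (−6.84) and WNT5A up (3.37). Immediate early and labile genes were higher in 8 and lower in 5 of 32 (0.39), ID2 at 709 ± 44.9 against 25.4 ± 3.95 and IER3 at 1862 ± 148 against 16943 ± 4166. KRAB zinc finger genes were higher in 3 and lower in 1 of 54 (3 and 0 over the list alone, 0.57), ZNF37A (0.75) and ZNF770 (0.54) among the higher. The medians of these last 2 lists, 0.29 and 0.18, turned to −0.014 and −0.12 when scaled to the ribosomal protein genes. Interferon genes were higher in 4 and lower in 6 of 19 (4 and 7 over the list alone, 0.56), with IFITM3 up (1.74) and the RNA sensor DDX58 down (−2.14). Unfolded protein response genes were higher in 4 and lower in 5 of 20 (0.78), TRIB3 among the lower (−1.59).

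In 3 lists the median, mean and test differed in sign. The p53 targets were higher in 2 and lower in 5 of 20, with a median of 0.00046, a mean of −0.23 and a camera direction of lower (adjusted p = 0.59); scaled to the ribosomal protein genes the median was −0.30. The cell cycle inhibitor CDKN1A fell from 920.2 ± 67.0 to 258 ± 42.3. S phase genes were higher in 7 and lower in 6 of 24, with a median of −0.022, a mean of 0.084 and a camera direction of higher (adjusted p = 0.78), TYMS up (1.65) and MCM4 down (−1.55). TGF-beta pathway genes were higher in 6 and lower in 5 of 23 (7 and 5 over the list alone), with a median of −0.038, a mean of 0.33 and a camera direction of lower (adjusted p = 0.99). LTBP1, which anchors latent TGF-beta in matrix, was up (7.16), and the activin subunit INHBA fell from 2519 ± 275 to 177 ± 22.5. Of 14 markers of leukocytes or endothelium only the monocyte gene CD14 was abundant enough to test (1.16, limma adjusted p = 0.11), so that list had no camera test. With an estimated correlation the 10 lists called at 0 min stayed below an adjusted p of 0.05 in camera, the highest being 0.020 for the EMT factors.

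**Figure D2:**
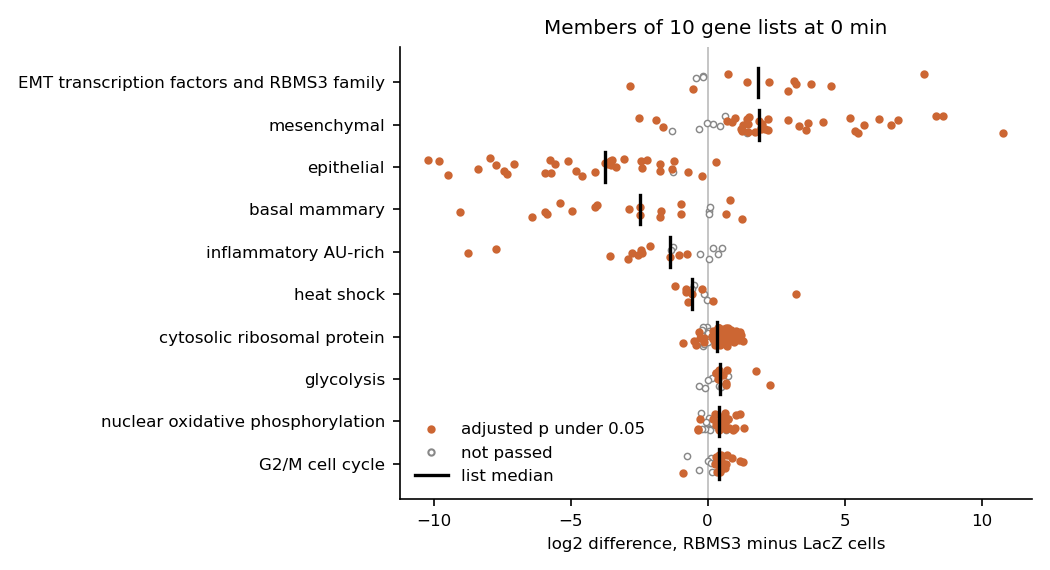
Log2 difference between RBMS3 and LacZ cells at 0 min for each tested member of 10 gene lists, with filled points for genes past the limma test and a black bar at the list median. Epithelial genes lie mostly below 0, with a median of −3.74, and mesenchymal genes mostly above, with a median of 1.87.

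The same contrast between the lines was tested at each later time. limma called 1797 genes higher and 1809 lower in RBMS3 cells at 90 min, 1961 and 2038 at 180 min, and 2118 and 2141 at 360 min. Between 0 and 360 min, 2663 genes were called in the same direction at both times and 97 in opposite directions, and 2060 were called in 1 direction at all 4 times. The estimates at 0 and 360 min, which share no library, correlated across genes at a Pearson r of 0.784; genes are not independent replicates. KRT14, a basal keratin, differed by 1.26 in RBMS3 cells at 0 min and by −1.49 at 360 min on the log2 scale.

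At 360 min FBLN5 was 1994 ± 68.1 in RBMS3 and 0.384 ± 0.666 in LacZ cells (log2 10.59), POSTN 1089.7 ± 95.6 against 0.196 ± 0.339 and UCHL1 1003 ± 51.2 against 0.681 ± 1.18. FRMD3, a FERM domain gene, was at 777 ± 41.2 (log2 8.51). BGN was 370.2 ± 70.4 against 1.41 ± 1.24. CADM3 (1085 ± 33.5) and RTN1 (175 ± 28.9) were at 0 in LacZ cells, at least 346-fold and 55.8-fold higher in RBMS3 cells. CDH1, the E-cadherin of epithelial junctions, was 520.1 ± 38.4 in LacZ cells and 0 in RBMS3 cells, at least 172-fold lower. The P-cadherin gene CDH3 was 1749 ± 28.1 against 2.84 ± 2.60. MAL2, ESRP1, KLK5, AP1M2, IL1B, IL1A and RAB25 were also at 0 in RBMS3 cells, between at least 111-fold lower (RAB25) and at least 513-fold lower (MAL2). LAD1 was 1038 ± 62.8 against 1.26 ± 2.19.

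At this time 12 lists were called by camera. Higher in RBMS3 cells were the EMT factors (9 higher and 3 lower of 14, also over the list alone, median 1.46, adjusted p = 0.0077), mesenchymal genes (30 and 3 of 43, or 32 and 3 over the list alone, median 1.63, 3.5e-15), ribosomal proteins (32 and 10 of 78, or 33 and 11 over the list alone, median 0.16, 7.7e-04), oxidative phosphorylation (21 and 1 of 44, or 23 and 1 over the list alone, median 0.27, 1.4e-05) and cholesterol synthesis (15 and 1 of 21, also over the list alone, median 0.94, 1.9e-06). The ribosomal protein call was lost at an adjusted p of 0.061 with an estimated correlation, and that median was 0.0076 when scaled to the list itself. In the cholesterol list FDFT1, which makes squalene, was 1460.1 ± 131 in RBMS3 and 536 ± 19.4 in LacZ cells, HMGCS1 626 ± 54.9 against 259 ± 34.2, and LSS was up by 1.35. IGFBP3 of the mesenchymal list was 3078 ± 234 against 65.2 ± 22.8. Lower in RBMS3 cells were epithelial genes (33 lower and 2 higher of 35, median −3.88, camera adjusted p = 6.7e-24), basal mammary genes (19 and 1 of 21, median −2.17, 4.4e-21), luminal mammary genes (5 and 1 of 8, or 5 and 2 over the list alone, median −2.17, 0.015), inflammatory transcripts (14 and 0 of 19, or 16 and 0 over the list alone, median −2.84, 5.2e-09), mitochondrially encoded genes (7 and 0 of 13, median −0.31, 8.7e-06), interferon genes (11 and 2 of 19, median −1.28, 0.0050) and heat shock genes (8 and 2 of 13, or 9 and 2 over the list alone, median −0.37, 0.035). Where no second count is given, the count over the list alone was the same. CXCL1, a neutrophil chemokine, was 190.0 ± 14.1 in LacZ and 12.1 ± 2.27 in RBMS3 cells, MT-ND1 2289 ± 81.5 against 794 ± 20.9, and ISG15, an interferon-induced modifier, 134 ± 15.4 against 39.1 ± 13.3. Glycolysis (6 higher, 3 lower; camera adjusted p = 0.34), G2/M (7 and 7; 0.85) and Wnt genes (3 and 8, or 3 and 9 over the list alone; 0.053) were not called, nor were the other 7 lists tested, among which the unfolded protein response had a median of 0.084, a mean of −0.076 and a camera direction of lower. Scaled to the ribosomal protein genes, 1558 genes were higher and 2778 lower at 360 min, and the median of all genes was −0.16.

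In LacZ cells the loss of RNA after transcription was blocked was read from 360 min against 0 min. IER5, an immediate early gene, fell from 751 ± 104 to 3.97 ± 3.36 (log2 −7.46, limma adjusted p = 3.2e-09), DUSP6, a phosphatase that limits ERK signalling, from 1143 ± 317 to 22.2 ± 14.2, and TRIB1 from 177 ± 18.7 to 2.14 ± 3.71. The linker histone gene H1-3 fell from 333 ± 52.4 to 0, at least 106-fold, and H2AC13, H1-4, H2AC14 and H1-5 changed by −6.85, −6.77, −6.02 and −5.80 on the log2 scale. RPH3A went from 55.0 ± 6.73 to 0, at least 17.5-fold lower. Among the rises, the 5S ribosomal RNA gene RNA5S1 went from 48.1 ± 16.8 to 1371 ± 165 (log2 4.87, limma adjusted p = 1.0e-10), the mitochondrial tRNA gene MT-TV from 478 ± 62.6 to 9993 ± 1537 (4.38), MT-TD from 9.27 ± 1.88 to 231 ± 41.8 (4.50) and SNORD118, the U8 small nucleolar RNA, from 1.24 ± 1.09 to 269.8 ± 64.5 (7.05). SNORD46 (5.34), RNU6-37P (5.19), SNORD3B-1 (4.42), SNORD87 (3.56) and HHIP (3.76) followed. SMIM11A (5.86) and SMIM11B (−6.43) are near-identical copies that share reads, so their opposite changes are uncertain. Histone, snoRNA and tRNA values depend on how a kit that primes on poly(A) reads RNAs that mostly lack it. limma called 416 genes higher and 331 lower at 90 min, 938 and 831 at 180 min, and 1800 and 1642 at 360 min. In fits on only the compared groups the counts were 13 and 74, 70 and 317, and 499 and 920. The 90 min count ranged from 392 without LacZ replicate 1 at 90 min to 1161 without LacZ replicate 1 at 0 min, and was 415 without LacZ replicate 3 at 90 min. Scaled to equal totals, 845 genes were higher and 2219 lower at 360 min, 409 and 1086 at 180 min, and 287 and 396 at 90 min. Scaled to the ribosomal protein genes, the counts were 135 and 4617, 105 and 2437, and 101 and 871. The median of all genes was −0.15 at 360 min with equal totals. With ribosomal protein scaling it was −0.19, −0.32 and −0.50 at the 3 times, against 0.0022, 0.032 and 0.029 in the main fit.

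Immediate early and labile genes fell in 29 of 32, with 0 rising, also over the list alone (median −3.35, camera adjusted p = 3.9e-29). JUN went from 949.5 ± 97.3 to 31.4 ± 14.9 and IER3 from 16943 ± 4166 to 418 ± 18.6. EMT factors fell in 6 and rose in 1 of 14, also over the list alone (median −1.09, camera adjusted p = 3.7e-05). SNAI2 went from 471 ± 223 to 38.7 ± 12.1 (−3.47), and FOXC2 (−3.57), FOXC1 (−2.37), SOX9 (from 923 ± 192 to 227 ± 31.5), TWIST1 (−1.44) and SOX4 (−1.21) fell, while RBMS2 rose (0.49) except under ribosomal protein scaling, where it was −0.042. RBMS1 (−0.34), ZEB1 (−0.17), ZEB2 (−1.97), TWIST2 (−0.20) and TCF4 (−0.49) did not pass. Inflammatory transcripts fell in 9 of 19 and rose in 0, also over the list alone (median −0.86, camera adjusted p = 8.7e-04), with NFKBIA, the inhibitor of NF-κB, falling by 5.48 on the log2 scale from 1141 ± 286. KRAB zinc finger genes fell in 14 and rose in 1 of 54, also over the list alone (median −0.70, 0.0022), ZNF212 by 2.49. Mitochondrially encoded mRNAs fell in 11 of 13, also over the list alone (median −1.01, camera adjusted p = 1.9e-16), MT-ND3 from 15298 ± 992 to 2117 ± 64.5 and MT-ND6 from 1559 ± 47.1 to 106 ± 30.0. Smaller falls were called by camera in p53 targets (4 of 20, SESN2 −4.40, adjusted p = 0.013), G2/M genes (9 lower and 2 higher of 25, or 11 and 2 over the list alone, KIF23 −0.75, 0.0089), the TGF-beta pathway (6 of 23, SMAD3 −0.85, 0.010) and RNA decay genes (9 lower and 2 higher of 35, or 10 and 2 over the list alone, YTHDF2 from 721 ± 37.8 to 188 ± 2.63, 0.010).

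In the same comparison ribosomal protein genes rose in 68 of 78 and fell in 0 (71 and 0 over the list alone, median 0.55, camera adjusted p = 1.9e-39), RPL37 from 7049 ± 1246 to 14873 ± 1023. Oxidative phosphorylation genes rose in 38 of 44 and fell in 0 (40 and 0 over the list alone, median 0.55, 4.5e-18), with COX6A1 going from 1144 ± 357 to 2228 ± 87.7. Glycolysis genes rose in 12 and fell in 1 of 18, also over the list alone (median 0.37, camera adjusted p = 5.3e-06), LDHA from 4829.5 ± 138 to 9202 ± 411 and PFKM the lower one (−0.76). Mesenchymal genes rose in 9 and fell in 2 of 43 (8 and 2 over the list alone, median 0.25, camera adjusted p = 0.038), with TAGLN up (0.78) and CCN1 (−4.08) and CCN2 (−1.86), both immediate early targets, down. With libraries scaled to equal totals, 3 mesenchymal genes were higher and 3 lower, with a mean of −0.021. Under ribosomal protein scaling the medians were 0.014, 0.0098, −0.17 and −0.20, so the last 2 turned. The first is held near 0 by the scaling itself. With an estimated correlation, camera kept the calls of all 13 lists. The other 9 lists tested were not called; in 3 of them the signs differed. Epithelial genes had a median of 0.24, a mean of −0.024 and a camera direction of higher (adjusted p = 0.57), luminal genes 0.20, −0.14 and lower (0.22), and cholesterol genes 0.16, −0.026 and higher (0.59). These 3 medians were negative under ribosomal protein scaling.

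The same series in RBMS3 cells gave 967 genes higher and 789 lower at 90 min, 1629 and 1503 at 180 min, and 2308 and 2244 at 360 min in limma. At 360 min JUN had gone from 823 to 38.9, IER5 from 600.2 to 7.77, DUSP6 from 319.5 to 3.59 and NFKBIA from 1286 to 10.7, while MT-TV had gone from 363 to 5817 and RNA5S1 from 43.6 to 321 (means of 3 libraries). Between the lines, which share no library, 1137 genes fell in both where independent lists would give 305, 1047 rose in both where they would give 343, and 90 went opposite ways. The estimates at 360 min correlated across genes at a Pearson r of 0.619. Scaled to equal totals, RBMS3 cells had 1307 genes higher and 2991 lower at 360 min and 1109 and 1889 at 180 min. Scaled to the ribosomal protein genes, they had 782 and 3775 at 360 min and 973 and 1955 at 180 min. The median of all genes was then −0.38 at 360 min and −0.15 at 180 min. Against 90 min in place of 0 min, 922 genes were higher and 1010 lower at 360 min in limma, and 1424 and 1563 in edgeR on estimated reads.

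Among 12 lists called at 360 min in RBMS3 cells, immediate early genes fell in 31 of 32 (31 lower and 1 higher over the list alone, median −4.10, camera adjusted p = 9.1e-27), EMT factors in 8 of 14 with 1 higher (median −1.27, 2.2e-04), inflammatory transcripts in 13 of 19 (median −2.15, 8.1e-06) and mitochondrially encoded genes in 12 of 13 (12 and 1 over the list alone, median −1.60, 4.8e-17). G2/M genes fell in 17 and rose in 1 of 25 (median −0.59, 5.9e-07), and p53 targets fell in 8 and rose in 2 of 20 (median −0.59, 0.032). Ribosomal proteins rose in 57 of 78 (59 over the list alone, median 0.38, 1.4e-19), oxidative phosphorylation genes in 33 of 44 (34 over the list alone, median 0.52, 4.1e-13), and cholesterol synthesis genes in 14 of 21 with 1 lower (median 0.77, camera adjusted p = 2.7e-05). DHCR7, the last enzyme of that pathway, went from 428 ± 29.6 to 1004 ± 47.3. Under ribosomal protein scaling the cholesterol median was 0.38, and the ribosomal protein median of −0.0051 is held near 0 by the scaling itself. This scaling shifts every gene, with a median of −0.38 over all genes, so it lowers the oxidative phosphorylation median as well. Luminal (4 lower of 8), KRAB zinc finger (13 lower and 2 higher of 54, or 12 and 2 over the list alone) and interferon genes (4 lower of 19) each had a camera adjusted p of 0.032, lost at 0.052, 0.11 and 0.10 with an estimated correlation. Glycolysis genes, which were called higher in LacZ cells, were higher in 4 and lower in 7 of 18 here (5 and 7 over the list alone, camera adjusted p = 0.82). S phase genes had a median of 0.17, a mean of −0.028 and a camera direction of higher (adjusted p = 0.46), and heat shock genes −0.079, −0.19 and higher (0.92). Where no second count is given, the count over the list alone was the same.

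**Figure D3:**
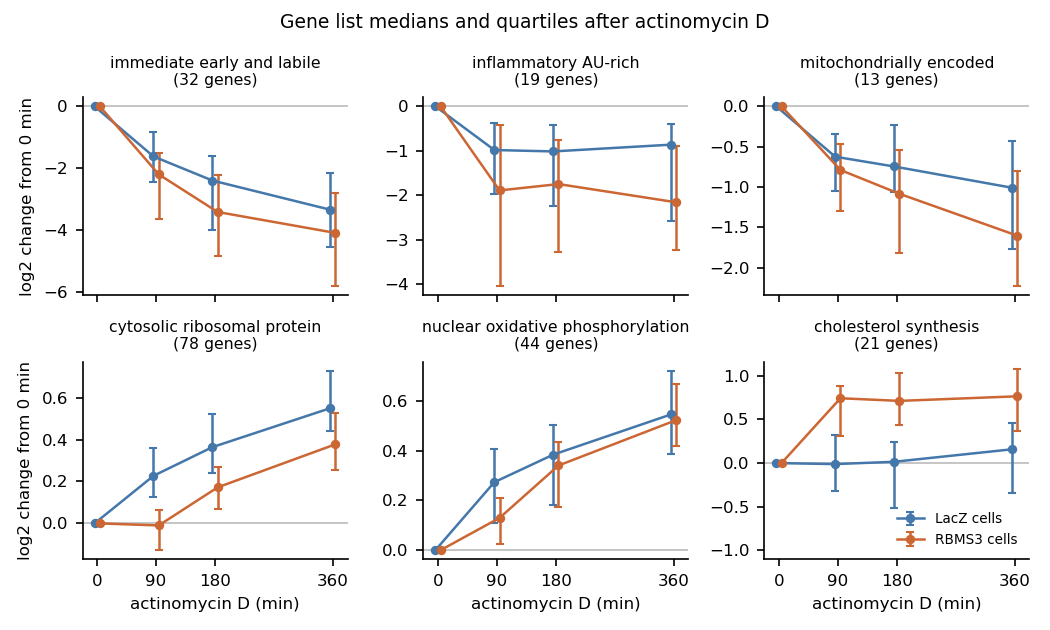
Median log2 change from 0 min, with quartiles, of the members of 6 gene lists in LacZ and RBMS3 cells by minutes of actinomycin D. Immediate early genes reached −3.35 in LacZ and −4.10 in RBMS3 cells at 360 min, and cholesterol synthesis genes stood at 0.74 in RBMS3 and −0.012 in LacZ cells by 90 min.

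The series asks which transcripts are lost at another rate when RBMS3 is present, and the difference in slope between the lines addresses it. KRT14, a basal keratin, went from 6059 ± 139.6 at 0 min to 791 ± 83.2 at 90 min and 1184 ± 21.4 at 360 min in RBMS3 cells, and from 2555 ± 465 to 2517 ± 139 and 3330.4 ± 254 in LacZ cells (slope difference −0.36 per hour, limma adjusted p = 3.7e-09). Cholesterol synthesis genes gained share in RBMS3 cells, where NSDHL went from 290.4 ± 36.7 to 605 ± 63.1 at 90 min and 614 ± 63.8 at 360 min, against 465 ± 79.0, 445 ± 26.9 and 454 ± 47.2 in LacZ cells (0.15 per hour, adjusted p = 0.012). TBL1X, a corepressor subunit, rose from 77.6 ± 11.9 to 586 ± 42.9 by 90 min in RBMS3 cells and stood at 7.88 ± 4.68 and 7.41 ± 3.35 in LacZ cells (0.60 per hour, adjusted p = 0.019). limma called 626 genes, 355 with a higher slope in RBMS3 cells and 271 with a lower slope. TMM factors gave 499 higher and 229 lower, ribosomal protein scaling 577 and 203, and equal library totals 314 and 308. On estimated reads, a setting added after the results were seen, limma called 1057 genes with equal totals (492 higher and 565 lower) and 1045 with a median ratio (525 and 520).

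Rises and falls here are slopes of a line that passed in limma, and alone means that the slope of the other line did not pass. Of the 355 genes, 204 rose in RBMS3 cells alone, 84 rose in both lines, 41 fell in LacZ cells alone, 17 fell in LacZ and rose in RBMS3 cells, and 9 fell in both. The 10 largest among genes with a mean of at least 50 were PGPEP1 (0.82), TBL1X, LHX1-DT (0.49), the nucleotide receptor P2RY2 (0.47), the transcription factor SOX15 (0.43), SFTA1P (0.43), HS3ST2, which modifies heparan sulfate (0.42), the adrenergic receptor ADRA1B (0.42), COL13A1 (0.41) and CDK19 (0.41), with limma adjusted p from 1.1e-04 (SOX15) to 0.047 (CDK19). HS3ST2 went from 13.0 ± 6.40 to 137 ± 19.9 at 90 min in RBMS3 cells and from 107 ± 16.0 to 118 ± 29.2 in LacZ cells. Of the 271 genes, 119 fell in RBMS3 cells alone, 58 rose in LacZ cells alone, 39 fell in both lines, 38 rose in LacZ and fell in RBMS3 cells, 16 rose in both and 1 passed in neither. The 10 largest by the same rule were CDH3 (−0.65), CXCL1 (−0.64), TXNIP, a brake on glucose uptake (−0.60), MT-TQ (−0.59), IRX3 (−0.57), HHIP (−0.57), PATJ (−0.52), LNPK (−0.46), the DNA damage kinase ATM (−0.45) and GNPDA2 (−0.43). CXCL1 went from 491 ± 21.0 to 12.1 ± 2.27 over 360 min in RBMS3 cells and from 356 ± 100.3 to 190.0 ± 14.1 in LacZ cells (limma adjusted p = 1.1e-05). TXNIP went from 769.6 ± 39.9 to 31.7 ± 12.8 against 76.9 ± 16.3 to 63.5 ± 5.31. In PGPEP1, CDK19 and LNPK the factor between table and estimated reads ranged 18.7-fold, 6.75-fold and 5.58-fold across libraries. From 90 to 360 min in RBMS3 cells, PGPEP1 changed by 3.24 in the table (limma adjusted p = 0.016) and by −0.059 on estimated reads (edgeR adjusted p = 0.96). PATJ changed by −2.55 in the table (limma adjusted p = 0.010) and by −0.57 on estimated reads (edgeR adjusted p = 0.47). The slope fit was repeated on the estimated reads of all 24 libraries under these 2 scalings. Of the 626 calls, 618 could be tested, and 530 kept call and direction with equal totals and 528 with a median ratio. Among the 20 genes above, PGPEP1 (−0.014 and −0.012 per hour), COL13A1, CDK19, IRX3, HHIP, PATJ and LNPK did not pass in either fit.

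By list, camera called cholesterol synthesis genes to the RBMS3 side, with 8 of 21 higher and 0 lower (12 and 2 over the list alone, median 0.095 per hour, adjusted p = 4.9e-06), among them MVK (0.26), HMGCS1 (0.13) and SQLE (0.12). Heat shock genes had 2 of 13 higher, HSP90AB1 (0.11) and DNAJB1 (0.11), with a median of 0.021 and an adjusted p of 0.032, lost at 0.052 with an estimated correlation. To the other side, basal mammary genes had 7 of 21 lower and 2 higher (9 and 3 over the list alone, median −0.068, camera adjusted p = 8.2e-04), with KRT17 and KRT5 at −0.28. Mesenchymal genes had 4 of 43 lower and 2 higher (5 and 2 over the list alone, median −0.062, 0.0042). The lower ones were TGFBI (−0.14), TAGLN (−0.14), the fibronectin gene FN1 (−0.13) and SPARC (−0.070), and the higher ones CD44 (0.10) and CDH2 (0.10). G2/M genes had 9 of 25 lower (12 over the list alone, median −0.067, 3.6e-05), such as BUB1 (−0.15). On estimated reads BUB1 was −0.065 with equal totals (limma adjusted p = 0.038) and −0.061 with a median ratio (0.055). CENPF, TOP2A and BIRC5, the other members named by the rule, passed in neither fit, while camera called the list in both (medians −0.050 and −0.046). Glycolysis genes had 5 of 18 lower (8 lower and 1 higher over the list alone, median −0.051, 3.6e-05), such as LDHA (−0.15), and mitochondrially encoded genes 4 of 13 (8 over the list alone, median −0.043, camera adjusted p = 1.4e-05), such as MT-ND1 (−0.19) and MT-CO1 (−0.16). Interferon genes had 2 of 19 lower, IFI6 (−0.39) and IFITM3 (−0.13) (4 over the list alone, median −0.12, 0.0042), and inflammatory transcripts 2 of 19, CXCL1 and CXCL3 (−0.66) (3 over the list alone, median −0.080, 0.015). Immediate early genes had 2 of 32 lower, ID1 (−0.29) and GADD45A (−0.10) (3 over the list alone, median −0.094, 0.0042), and ribosomal proteins 6 of 78 lower and 1 higher (17 and 6 over the list alone, median −0.016, 0.0042). These last 2 calls were lost at adjusted p of 0.19 and 0.13 with an estimated correlation. On estimated reads DNAJB1 passed in neither fit, and the inflammatory call was lost at 0.057 with equal totals. None of the 14 EMT factors and RBMS family members passed (median 0.0050, mean 0.0037, camera direction lower, adjusted p = 0.87; 0 over the list alone). On estimated reads TWIST1 passed in both fits (−0.17, adjusted p = 0.040 and 0.042) and SOX4 with equal totals (−0.093, 0.045). In 5 other lists not called the signs also differed: oxidative phosphorylation (median −0.0027, camera direction higher, adjusted p = 0.82), p53 targets (median −0.016, mean 0.0096, higher, 0.91), the TGF-beta pathway (median 0.0057, mean −0.015, higher, 0.14), the unfolded protein response (median −0.014, higher, 0.82) and RNA decay (median −0.0064, higher, 0.37). Members named here outside the naming rule were chosen after their values were seen.

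In the direction of the slope, the lines' changes from 0 min differed by a median of 0.68 at 90 min, 0.79 at 180 min and 0.99 at 360 min over the 626 genes. RBMS3 cells moved by a median of 0.53 from 0 to 90 min and 0.30 from 90 to 360 min, and LacZ cells by −0.12 and 0.012. KRT14 fell by 2.94 on the log2 scale in RBMS3 cells by 90 min, KRT17 by 2.16, TXNIP by 3.94, CXCL1 by 4.00 and CDH3 by 4.74. With the 0 min libraries of both lines left out, a setting added after the results were seen, limma called 3 genes, all among the 626, at a median SE of 0.0867 against 0.0633 per hour. These were IRX1 (0.77 per hour, adjusted p = 0.041), RNA5S1 (−0.54, 0.034) and TSC22D1 (−0.40, 0.034), and 805 genes had an unadjusted p under 0.05. In that fit the cholesterol median was 0.0018 (camera adjusted p = 0.88), and camera called ribosomal proteins (0.021, 2.9e-05) and mitochondrially encoded genes (−0.029, 3.0e-04), lost at 0.15 and 0.24 with an estimated correlation.

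**Figure D4:**
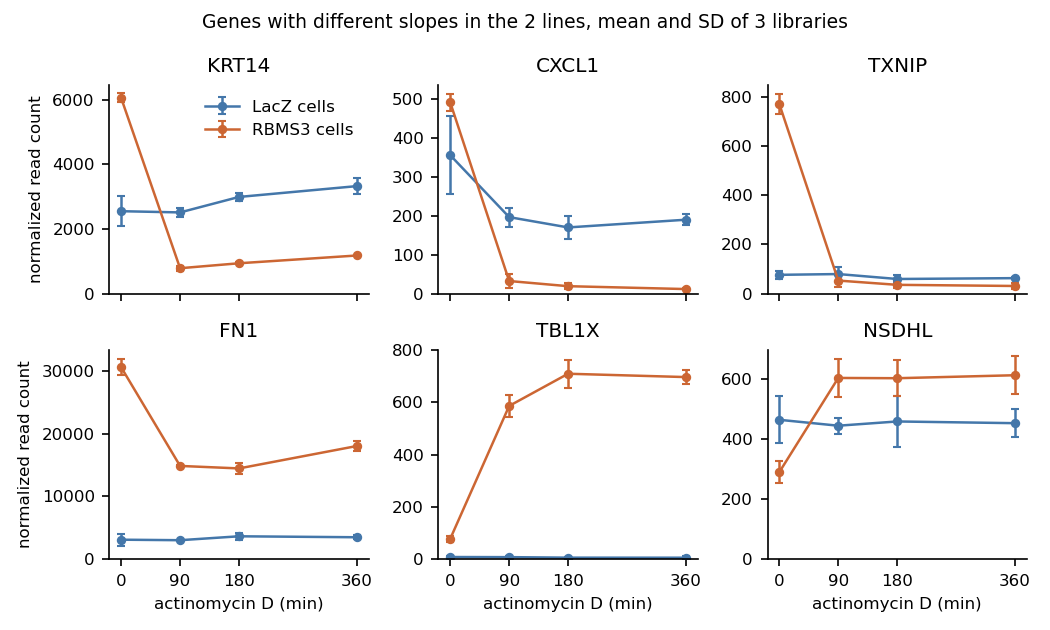
Normalized count (mean ± SD, n = 3) of KRT14, CXCL1, TXNIP, FN1, TBL1X and NSDHL in LacZ and RBMS3 cells by minutes of actinomycin D. In RBMS3 cells KRT14 stood at 6059 ± 139.6 at 0 min and 791 ± 83.2 at 90 min, and NSDHL at 290.4 ± 36.7 and 605 ± 63.1.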

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

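The tests of a step between 0 and 90 min and of slopes on estimated reads were written after the results were seen. The tests of floor, scaling, the range of the factor between table and reads, and AUAUA content were written before. The rules for that factor and for AUAUA content were later set aside, as given below. The results here are flagged because the change with time differed between LacZ and RBMS3 cells in a direct test of that difference, which 626 genes passed in limma and 11 lists in camera.

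Slopes were higher in RBMS3 cells for PGPEP1 (0.82 per hour), TBL1X (0.60), LHX1-DT (0.49), P2RY2 (0.47), SOX15 (0.43), SFTA1P (0.43), HS3ST2 (0.42), ADRA1B (0.42), COL13A1 (0.41) and CDK19 (0.41). From 90 to 360 min in RBMS3 cells, PGPEP1 changed by 3.24 in the table and by −0.059 on estimated reads (edgeR adjusted p = 0.96), and PATJ by −2.55 and −0.57 (0.47). Slopes were lower for CDH3 (−0.65), CXCL1 (−0.64), TXNIP (−0.60), MT-TQ (−0.59), IRX3 (−0.57), HHIP (−0.57), PATJ (−0.52), LNPK (−0.46), ATM (−0.45) and GNPDA2 (−0.43). Among the lists called by camera, the median slope difference was 0.095 for cholesterol synthesis and 0.021 for heat shock genes. It was −0.062 for mesenchymal, −0.068 for basal mammary, −0.094 for immediate early and labile, −0.080 for inflammatory, −0.016 for ribosomal protein, −0.051 for glycolysis, −0.043 for mitochondrially encoded, −0.067 for G2/M and −0.12 for interferon response genes. The calls of the heat shock, immediate early and ribosomal protein lists were lost at adjusted p of 0.052, 0.19 and 0.13 with an estimated correlation.

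Values near the floor in 1 line at 0 min do not account for the 626 genes as a whole. The share called was 6.18% among genes with a mean of at least 20 in both lines at 0 min, against 5.18% among all, a ratio of 1.19. This filter keeps genes that neared the floor later, so floor effects at later times stay open. Library scaling does not account for the 626 genes either, with at least 88.5% of the calls kept in direction under each of the 3 other scalings. The factor between table and estimated reads, which was not shown to be a length correction, is not the whole cause. At least 84.3% of the calls kept call and direction on estimated reads of all 24 libraries under 2 scalings. The factor stays open as a cause for those that did not, such as PGPEP1, COL13A1, CDK19, IRX3, HHIP, PATJ and LNPK. It ranged less in called genes in 12 libraries, none of RBMS3 cells at 0 min (a ratio of 0.818). By the rule written beforehand, this counts against the factor as a cause. That rule was set aside and the ratio decides nothing. Genes with a wide range vary more in the table (median SD 0.377 against 0.198) and are harder to call. A state of the RBMS3 cells at 0 min, such as a difference in handling or in medium, may have ended by 90 min. The line difference at 90 min was already 0.690 of that at 360 min. Free of error, a steady difference would give 0.25 and a full step 1. Both differences use the same 0 min libraries, which also entered the choice of the 626 genes. Error at 0 min can therefore move the ratio toward 1. This ratio cannot tell such a state from a fast early effect of RBMS3 on RNA loss. Of the 355 genes with a higher slope, 204 rose in RBMS3 cells alone and 84 in both lines, where alone means that the other line's slope did not pass. Another 17 rose in RBMS3 and fell in LacZ cells, 41 fell in LacZ cells alone and 9 fell in both. Slower loss raises a share only as other transcripts are lost. In RBMS3 cells the ribosomal protein median was −0.0097 at 90 min and 0.38 at 360 min, and the oxidative phosphorylation median 0.13 and 0.52. The ribosomal protein list was itself called to a lower slope in RBMS3 cells, so it may not be a neutral measure of that loss. These values cannot decide whether slower loss is the whole cause for the genes that rose. A state at 0 min and an early effect on loss stay open for all these genes. TXNIP, a gene induced by glucose, fell from 769.6 to 53.6 between 0 and 90 min in RBMS3 cells while NSDHL rose from 290.4 to 605, and EPCAM at 0.707 in RBMS3 cells at 0 min leaves no room for a share of LacZ cells large enough to move these genes. When the lines were regrouped at random within each time 100 times, each line centred, the real grouping gave 544 genes and the highest other 6 (1 of 100).

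For each comparison of 3 against 3 libraries, the 10 ways to split them are too few for a share under 0.05, and the real grouping was 1 of 10 in each. RBMS3 against LacZ cells gave 4534 genes at 0 min (highest other split 2), 3606 at 90 min (1), 3999 at 180 min (2) and 4259 at 360 min (2). Against 0 min, LacZ cells gave 747 at 90 min (3), 1769 at 180 min (96) and 3442 at 360 min (2), and RBMS3 cells 1756 (3), 3132 (1) and 4552 (2).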

How the results depend on the processing

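The slope from 90 to 360 min and the slopes on estimated reads were chosen after the results were seen. A filter of at least 20 in both lines at 0 min was added later than the others but before its result was seen. The other settings were fixed before. The count tests on reads recovered from the table were not run, since its values are not whole reads, and depth limits genes near 3 reads per library. Where no cause is given, the cause was not tested. Counts of called genes stayed within 1.5 times under both pseudocounts, both filters, all 3 scalings and the block of replicate numbers, which gave 4528, 3588, 3995 and 4250 between the lines, 748, 1770 and 3453 in LacZ cells, 1728, 3130 and 4529 in RBMS3 cells and 586 for slopes. The labels do not pair the replicates: same-numbered libraries deviated with a mean r of 0.0044, 1 of 84 pairs was over 0.1 and 12 of 24 libraries lay closest to their own number. Fits on only the compared groups gave 87, 387 and 1419 genes in LacZ cells at 90, 180 and 360 min, and 1710, 3153 and 4641 in RBMS3 cells. Between the lines such fits kept 2911 of the 4534 calls at 0 min (64.2%) and 3256 of 3606 at 90 min. They kept 3343 of 3999 at 180 min and 3745 of 4259 at 360 min. A 2-fold minimum, which can only remove calls, left 2260, 1852, 2020 and 2141 between the lines, 230, 657 and 1377 in LacZ cells, 633, 1281 and 1992 in RBMS3 cells and 251 slopes over 6 h. The interaction at 360 min alone gave 940, and the slope from 90 to 360 min gave 3 genes and 2 lists. Slopes on estimated reads gave 1057 genes and 11 lists with equal totals and 1045 and 13 with a median ratio. With an estimated correlation, camera lost the immediate early, ribosomal protein, S phase and heat shock calls in both, at adjusted p of 0.064 to 0.32. With a median ratio it also lost the mitochondrially encoded (0.065), luminal (0.079) and inflammatory calls (0.14). With fry 19, 19, 20 and 20 lists were called where camera called 10, 12, 13 and 12. In RBMS3 cells against 90 min, edgeR on estimated reads called 364 genes at 180 min where limma on the table called 165, and 2987 at 360 min where it called 1932. Of 1877 table calls also tested there at 360 min, 1681 were called in the same direction and 3 in the opposite one. With the transcript files as attached in the record, the log2 ratio of RBMS3 between the lines was −0.287 at 0 min and −0.109 at 90 min, against 1.48 at 0 min by table column. Among genes named by the rule, directions turned for those that follow. Genes chosen after their values were seen were not checked for this. With a pseudocount of 5 the slope differences of ZEB2 and FOXC2 were −0.044 and −0.10. With equal totals RBMS3 at 360 min in LacZ cells was −0.16 and the slope of FOXC2 −0.0053. With TMM and with ribosomal protein scaling the slope of ZEB1 was 0.0071 and 0.0088. Ribosomal protein scaling also gave −0.081 for SNAI2 between the lines at 360 min and, in LacZ cells at 360 min, −0.50 for RBMS3, −0.042 for RBMS2, −0.0083 for S100A2, −0.057 for ALDOA and −0.079 for IFITM3, since it lowers every gene by the rise of that list. The slope from 90 to 360 min was negative for HS3ST2 (−0.019), ADRA1B (−0.040), FOXC2 (−0.018), SOX9 (−0.0079), INHBA (−0.023), HMGCS1 (−0.016) and SQLE (−0.015), and positive for ZEB1 (0.012), TWIST2 (0.018), TCF4 (0.025), TGFBI (0.0026), FN1 (0.032), KRT14 (0.044), KRT17 (0.025), KRT5 (0.058), RPL37 (0.0075), RPS25 (0.010), LDHA (0.0043), PGK1 (0.0094), ALDOA (0.028), PGAM1 (0.021) and IFITM3 (0.0063). On estimated reads the slopes with equal totals and with a median ratio were 0.016 and 0.020 for RBMS3, −0.014 and −0.012 for PGPEP1, −0.016 and −0.012 for RBMS1, 0.040 and 0.044 for ZEB1, −0.031 and −0.020 for ZEB2 and −0.17 and −0.17 for TWIST1, and FOXC2 was −0.0020 with equal totals. Leaving out 1 library at a time gave ranges of 392 to 1161 genes for LacZ cells at 90 min and 423 to 864 for slopes. In LacZ cells at 360 min RBMS3 ranged from −0.35 to 0.23, TWIST2 from −0.44 to 0.0086 and ZEB1 from −0.71 to 0.17, and between the lines SNAI2 ranged from −0.68 to 0.081 at 0 min and from −0.34 to 0.33 at 360 min. Slope differences ranged from −0.032 to 0.032 for FOXC2, −0.0046 to 0.057 for RBMS1, −0.092 to 0.0069 for RBMS3, −0.0074 to 0.13 for SNAI2, −0.024 to 0.032 for SOX9, −0.060 to 0.091 for ZEB1 and −0.037 to 0.25 for ZEB2. Ribosomal protein scaling kept 51.6% of the calls in LacZ cells at 360 min and reversed 96 of them.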

Other observations

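The tests of the small RNAs and of the replicate spread were written after their values were seen; the AUAUA hypothesis was written before. KRT7, a simple keratin, went from 10008 ± 254 to 23717 ± 880 over 360 min in RBMS3 cells and from 8259 ± 1247 to 11978 ± 160 in LacZ cells (slope difference 0.10 per hour, limma adjusted p = 0.0017). CDS1, a lipid enzyme, went from 20.4 ± 3.76 to 68.4 ± 8.91 in RBMS3 cells, against 594 ± 81.4 and 569 ± 14.5 in LacZ cells (0.27 per hour, adjusted p = 1.0e-04). INHBA, an activin subunit, went from 177 ± 22.5 to 545 ± 172 by 90 min in RBMS3 cells and fell from 2519 ± 275 to 1695 ± 92.0 in LacZ cells (0.26 per hour, adjusted p = 9.9e-05). ASNS, which makes asparagine, went from 162 ± 14.1 to 437 ± 51.0 by 90 min in RBMS3 cells and stood at 244 ± 78.0 and 242 ± 11.1 in LacZ cells (0.19 per hour, adjusted p = 0.0045). ID1, an inhibitor of differentiation factors, fell in both lines, from 5389 ± 178 to 158 (mean of 3) in RBMS3 cells and from 705 ± 295 to 74.3 ± 5.70 in LacZ cells (−0.29 per hour, adjusted p = 0.0028). At least 2-fold changes by 90 min numbered 41 higher and 189 lower in LacZ cells and 170 and 463 in RBMS3 cells.

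The first hypothesis was that transcripts lost less steeply with RBMS3 carry more AUAUA, the core of the element that RBMS proteins bind, in their longest annotated 3' UTR. Genes with a higher slope in RBMS3 cells held 1.18 per kb (330 genes) against 1.65 in genes not called (10444 genes), a difference of −0.467. By the rule written beforehand, a density at or below that of genes not called counts against the hypothesis. That rule was set aside. Of the 355 such genes 204 rose in RBMS3 cells alone, 84 rose in both lines and 17 rose in RBMS3 and fell in LacZ cells. A rise is a gain in share, which slower loss or another source can give. These genes therefore need not be genes of slower loss, and the comparison cannot decide the hypothesis. Genes with a lower slope held 1.73 per kb (238 genes). The AU content of the 3 classes was 50.7%, 56.3% and 56.9%, so the difference may follow base composition.

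Of 92 small non-coding RNA and mitochondrial tRNA genes tested, 27 rose and 10 fell in LacZ cells at 360 min (median 0.18), and 21 rose and 28 fell in RBMS3 cells (median −0.37). In LacZ and RBMS3 cells the medians were 1.17 and −0.82 for 16 mitochondrial tRNA genes, 0.23 and 0.70 for 32 snoRNA and scaRNA genes, and −0.21 and −0.72 for the other 44. Scaled to the ribosomal protein genes, the median of all 92 genes was −0.742 in RBMS3 cells and −0.33 in LacZ cells, and since members go both ways, this cannot tell a gain of poly(A) tails on these RNAs from a slower loss. No biological explanation was tested.

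The deposited values spread more between replicates than the estimated reads do. In the 3139 genes whose factor between table and reads ranged over 1.5-fold, the median SD within groups was 0.377 in the table and 0.217 in the reads, a ratio of 1.73. In an equal number of genes with a range of at most 1.1 the ratio was 1.00. Since genes were grouped by the ratio of table to reads itself, the comparison cannot tell whether a length correction is the source of the added spread. No biological explanation was tested.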
